A study of Mus musculus with 8 samples.

How the data were processed

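RNA from mouse spleen and lymph node samples that were wild-type or knockout for Aire was measured on 8 Affymetrix expression arrays, 2 for each of the 4 combinations of tissue and genotype. The labels give tissue, genotype and a letter, A or B, for each array. They give no cell type, sorting step, age or sex, and nothing in them says what the letters mark. Spleen and lymph node below therefore mean samples from these tissues, which need not be whole tissue. The values deposited by the authors are intensity values, 1 signal per probe set on a linear scale. Per the submitters' processing notes they come from MAS5; its version, target value and detection calls are not given in the sources used here. In these values the 2% trimmed mean of every array came to 250, so each array had been scaled before deposition.

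The table held 45101 probe sets, of which 64 control probe sets were left out. Of the 45037 others, 34945 carried exactly 1 gene symbol in the probe set table, 932 carried several and 9160 carried none. Gene names were matched to current symbols through a table of mouse gene names, and no coordinates were used. The medians of the arrays ranged over 0.28 on the log2 scale, more than the 0.2 fixed as the tolerance, so each array was shifted to the common median. Signals under the 20th percentile of all values, 9.58, were raised to that floor. Values were then taken to log2. Each gene was represented by the probe set with the highest mean over the 8 arrays, which gave 18193 genes. The 11557 genes above the pooled median signal of 59.0 on at least 2 arrays were tested.

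Tests were run in R 4.3.3 with limma 3.58.1. A linear model with a mean for each of the 4 groups was fitted to all 8 arrays, and moderated by empirical Bayes. It left 4 residual degrees of freedom, to which the prior added 2.96. From it 5 contrasts were taken: knockout minus wild-type in spleen, the same in lymph node, their average, their difference, and spleen minus lymph node averaged over genotypes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. All intervals are at 95%. The number of arrays limits the precision of every value. The labels do not say whether the arrays of a group come from separate animals. Their Xist or Y-linked signals differed between A and B, as given below, which argues against repeats of the same RNA. How many animals each array holds is not known. The p-values measure only the spread between these samples, part of which may be technical.

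Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over the lists within each contrast, and again with the correlation estimated from the residuals. There were 31 lists with 465 members, 16 of them of cell type markers and 15 of pathways or other groups. Older symbols were matched through synonyms, and 52 members without a match are not analysed here. The sex-linked list served only as a check of sample composition, and the spleen stromal identity list had 1 tested member and was not tested, since a list needed at least 3. For each list the members past the gene test were counted over all genes tested and also adjusted over the list alone. Limma's fry, which asks whether the members of a list move on balance in one direction without comparing them with other genes, was run beside it.

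The genes named were chosen by rule. Where fewer than 5 genes in a direction passed the threshold, those with the smallest unadjusted p were named up to 5, and said not to pass. Aire was named throughout, and for each list up to 4 members with the smallest p. Predicted or unnamed transcripts counted in the numbers only. The groups, the preprocessing, the contrasts, the tests, the lists, the naming rule and most alternatives were chosen before the data were examined.

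The procedure was tested on simulated data of the same shape with 200 of the 11557 genes changed in each of 20 runs. For the averaged knockout effect it called 7.20% of genes changed by 1 on the log2 scale, 75.2% of those changed by 2, 95.0% at 3 and 98.7% at 4. In spleen alone these shares were 0.800%, 26.1%, 76.5% and 92.5%, and in lymph node alone 1.10%, 29.2%, 76.9% and 91.6%. Each run mixed genes changed by 1, 2, 3 and 4, and many called genes ease the adjusted threshold for the rest. The shares therefore do not apply where few genes change. That no gene passed in the real data does not exclude changes of these sizes. By camera a list of 15 genes shifted by 1 had an unadjusted p under 0.05 in 20 of 20 runs and an unshifted list in 0 of 20. No adjustment over lists was made there, unlike in the real data. The simulated genes were independent, so these counts do not bear on lists whose members are correlated. The estimated correlation was 0.49 in the macrophage and 0.58 in the proliferation list.

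The alternatives fixed in advance were quantile normalization, no median scaling, no floor, adding the floor to each value, a floor at the 40th percentile, no filter, a filter at the 70th percentile, all probe sets, the mean of a gene's probe sets, the letter as a term, only the arrays of the groups compared, a trended robust prior, array weights, an estimated correlation for the list tests, and leaving out each array in turn. Added after the data were seen were genotype and letter as a random or a fixed block, the Y-linked genes as a covariate, leaving out both knockout arrays of a letter, and the letter as a term together with an estimated correlation.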

Results

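Gene expression was measured on 8 arrays from mice that were wild-type or knockout for Aire, the autoimmune regulator that drives display of tissue antigens in the thymus. The study concerned cells that express Aire outside the thymus. There were 2 arrays each of wild-type spleen, knockout spleen, wild-type lymph node and knockout lymph node, named A and B within a group. Median signal per array ranged from 53.8 to 65.3 on the deposited scale. The ratio of the 3' to the 5' control probe set ranged from 1.01 to 1.13 for Actb and from 2.99 to 4.53 for Gapdh. Differences are given on the log2 scale with their SE, and folds follow from them.

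The arrays of a group differed in sex-linked transcripts. In the wild-type A arrays Xist, the transcript of the inactive X chromosome, had a signal of 7624 in spleen and 7090 in lymph node, and the Y-linked gene Eif2s3y had 21.2 and 3.80. In the wild-type B arrays both were present, with Xist at 4585 and 3565 and Eif2s3y at 1749 and 1692. Both were also present in the knockout A arrays, with Xist at 5527 and 6355 and Eif2s3y at 1116 and 521. The knockout B arrays had Xist at 14.6 and 23.1 and Eif2s3y at 1968 and 1988. The mix of Xist and Y-linked signal thus differed between the genotypes compared.

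The targeted gene, Aire, was lower in all 4 knockout arrays than in any wild-type array, and its knockout signal stayed well above the floor of 9.58. In spleen its probe set had a mean signal of 5121 ± 118 (SD, n = 2) in wild-type and 1692 ± 967 (SD, n = 2) in knockout arrays. In lymph node the means were 3293 ± 341 (SD, n = 2) and 964 ± 245 (SD, n = 2). The knockout minus wild-type difference was -1.73 ± 0.46 in spleen, a 3.31-fold lower level, and -1.79 ± 0.46 in lymph node, a 3.46-fold lower level. The spleen difference was -1.11 without its knockout array A and -2.34 without B. Averaged over tissues it was -1.76 ± 0.33, 3.38-fold lower, with an interval of ± 0.77. An exact two-sided permutation of genotype within tissue over 36 assignments gave p = 0.0556, the smallest p these arrays can give. As the targeted gene, Aire was chosen before the tests. Its unadjusted limma p was 0.00101 for the averaged difference, 0.0072 in spleen and 0.00597 in lymph node. Over all genes tested the limma adjusted p was 0.237 for the averaged difference, 0.412 in spleen and 1 in lymph node, so Aire did not pass; with a trended robust prior its averaged adjusted p was 0.0492. The difference between the tissues in the knockout effect was 0.07 (adjusted p = 0.999). The place of the probe set relative to the deleted part of the gene is not given in the sources used here.

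**Figure D1:**
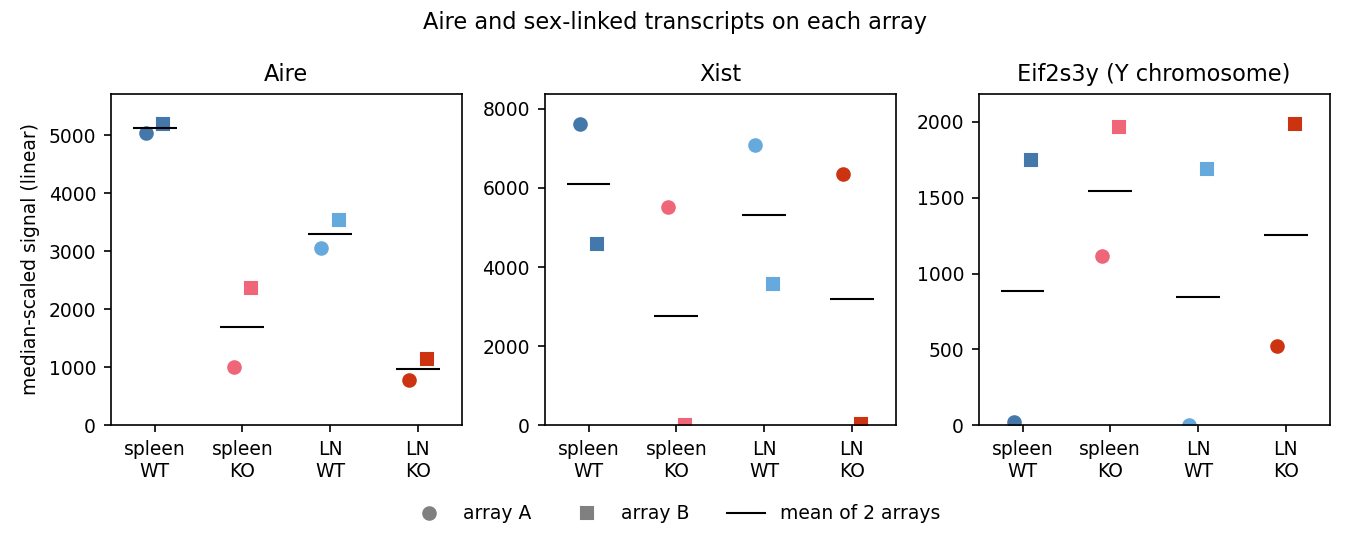
Signal of Aire, Xist and the Y-linked gene Eif2s3y on each of the 8 arrays, on a linear axis after scaling to a common median; points are arrays (circle A, square B) and lines are means of 2 arrays. The 4 knockout arrays have Aire signals from 791 to 2376 and the 4 wild-type arrays from 3052 to 5204.

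The question in spleen was what differed in expression when Aire was deleted. Macrophage, cell cycle, costimulatory, interferon-response, chemokine and platelet genes were higher as groups in knockout spleen by camera at its preset correlation. None of these 7 lists passed with an estimated correlation, the lowest adjusted p = 0.536 and the highest adjusted p = 0.631. No single gene passed correction, and 1 knockout array, A, carried much of the difference in several of these groups. The genes with the smallest p were led by the complement receptor C5ar1, which had signals of 12.1 and 25.1 in wild-type and 1868 and 537 in knockout spleen.

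C5ar1 was higher in knockout spleen by 5.84 ± 0.63, from wild-type signals near the floor; the difference was 4.94 without knockout array A, 6.74 without B and 3.21 for the mean of its probe sets. Cpq, a carboxypeptidase, was higher by 3.21 ± 0.36, at least 9.27-fold, since both wild-type arrays lay at the floor. Havcr2, an inhibitory receptor of T and myeloid cells, was higher by 3.42 ± 0.41 (at least 10.7-fold, with 1 wild-type array at the floor). Plau, the urokinase plasminogen activator, was higher by 3.03 ± 0.38 (8.18-fold) and Thumpd3 by 2.91 ± 0.36 (7.54-fold). Among genes with lower values, Tmem258 differed by -3.02 ± 0.36 (8.10-fold) and the Wnt ligand Wnt10b by -3.35 ± 0.42, at least 10.2-fold, with both knockout arrays at the floor. Chadl differed by -2.43 ± 0.34, Gstm4, a glutathione transferase, by -2.20 ± 0.33, and Pkp2, a desmosomal protein, by -2.78 ± 0.44. None of these genes passed, with limma adjusted p = 0.166 for C5ar1, Cpq, Havcr2, Plau, Thumpd3, Tmem258 and Wnt10b, 0.208 for Chadl, 0.262 for Gstm4 and 0.276 for Pkp2. For the mean of a gene's probe sets the difference was 1.42 for Thumpd3 and -1.63 for Tmem258.

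In camera tests 7 lists rose in knockout spleen. The macrophage list rose by a mean of 1.65 (13 of 15 tested members higher; adjusted p = 0.000384; adjusted p = 0.631 with an estimated correlation). Its members with the smallest p were Siglec1 (2.59), Cd5l (4.73), Adgre1 (1.17) and Mertk (2.11). Its mean log2 signal was 9.65 on knockout array A and 7.49 on B, against 7.41 and 6.43 in wild-type. The proliferation list rose by a mean of 1.34 (17 of 18 higher; adjusted p = 6.78e-05; adjusted p = 0.631 with an estimated correlation), with Nusap1 at 2.92, Mcm2 at 1.46, Ccnb2 at 2.67 and Top2a at 1.54. Its mean log2 signal was 8.87 on knockout array A and 6.63 on B, against 6.58 and 6.24. The platelet and megakaryocyte list rose by 2.71 over 3 genes (adjusted p = 0.0194; adjusted p = 0.575 with an estimated correlation), with Pf4, a platelet chemokine, at 4.96. The costimulation and coinhibition list rose by 0.76 (11 of 14 higher; adjusted p = 0.00158; adjusted p = 0.536 with an estimated correlation), with Cd86 at 2.22, Tnfrsf14 at 1.77, Tnfsf9 at 0.86 and Tnfsf4 at 1.89.

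The type I interferon response list rose by a mean of 0.62 in knockout spleen (11 of 16 higher), with Irf7 at 2.42, Oasl2 at 3.07 and Oasl1 at 1.30, while Mx1 was lower at -1.15. The interferon-gamma response list rose by 0.67 (8 of 12 higher), with the GTPases Iigp1 at 3.57 and Igtp at 1.65. The chemokine and cytokine list rose by 0.55 (15 of 22 higher), with Il10 at 2.22 and Ccl2 at 1.64. Each of the 3 lists had an adjusted p = 0.0194, and adjusted p = 0.536 with an estimated correlation. Over all genes tested, 0 members of these 7 lists passed. Adjusted over the list alone, 3 type I interferon, 2 interferon-gamma, 2 chemokine and 1 platelet gene passed, all higher: Irf7, Oasl1, Oasl2, Igtp, Iigp1, Il10, Ccl2 and Pf4. In the list of thymic tissue antigens that depend on Aire, which did not pass in spleen (adjusted p = 0.146), Csn2 was higher by at least 2.46. Both wild-type arrays lay at the floor for it, and it passed over the list alone.

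By limma 0 of 11557 genes passed in spleen, and 973 had an unadjusted p under 0.05, 446 higher and 527 lower in knockout, where chance gives 578. With a trended robust prior C5ar1 passed (adjusted p = 0.00525), and with all probe sets tested 2 probe sets without a gene name passed. Without median scaling the median of all genes moved from -0.09 to 0.02, and 578 of 976 genes at that p were higher. Groups did not overlap in 37.2% of genes, where chance gives 33.3%. Without knockout array A, 2 lists passed, costimulation (adjusted p = 0.00324) and type I interferon (adjusted p = 0.0202); the means were then 0.57 for macrophage (adjusted p = 0.312), 0.22 for proliferation (adjusted p = 0.378), and 1.43 for platelet, 0.44 for interferon-gamma and 0.24 for chemokine genes (each adjusted p = 0.182). Without knockout array B, 11 lists passed, but the type I interferon list did not (adjusted p = 0.362), and it also missed without wild-type array A (adjusted p = 0.185), as did the chemokine list (adjusted p = 0.0973). Without wild-type array B the interferon-gamma (adjusted p = 0.0624) and platelet lists (adjusted p = 0.213) missed. With a stricter filter the type I interferon mean was -0.05, and that list also missed with all probe sets (adjusted p = 0.0852) or the mean of probe sets (adjusted p = 0.0741). Without a filter the chemokine (adjusted p = 0.1) and interferon-gamma lists (adjusted p = 0.086) missed, as did the platelet list with a 40th percentile floor (adjusted p = 0.0706) or quantile normalization (adjusted p = 0.0509).

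In lymph node the same question was asked of the other pair of groups. By camera at its preset correlation, knockout lymph node had higher macrophage, cell cycle, interferon-response, chemokine and tissue antigen genes as groups. None of these 6 lists passed with an estimated correlation, the lowest adjusted p = 0.16 and the highest adjusted p = 0.699. Of 21 measured tissue antigen genes 4 were tested, and of these only the milk casein Csn2 passed over the list alone; with all 21 the mean was 0.45 (adjusted p = 0.225). No single gene passed correction.

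Foxd1, a forkhead transcription factor, was higher in knockout lymph node by 2.76 ± 0.33 (6.77-fold), with wild-type signals of 9.87 and 10.8, next to the floor. Fcgr2b, the inhibitory receptor for IgG, was higher by 2.88 ± 0.36 (7.37-fold), and Plau by 2.74 ± 0.38 (6.69-fold). Csn2 was higher by 4.04 ± 0.55, at least 16.4-fold, with both wild-type arrays at the floor and knockout signals of 163 and 152. Rnase4, a ribonuclease, was higher by 2.36 ± 0.35 (5.12-fold). Among genes with lower values, Slc16a9, a monocarboxylate transporter family member, differed by -2.21 ± 0.35 (4.61-fold), and Cacng7 by -2.96 ± 0.48, at least 7.76-fold. Flrt1 differed by -2.72 ± 0.49 (-2.09 without knockout array A and -3.36 without B), Fam228b by -2.34 ± 0.45 and the neuropeptide gene Npvf by -2.36 ± 0.47, at least 5.12-fold. None passed, with limma adjusted p = 0.485 for Foxd1, Fcgr2b, Csn2 and Plau, 0.528 for Rnase4, Slc16a9 and Cacng7, 0.615 for Flrt1 and 0.653 for Fam228b and Npvf. For the mean of a gene's probe sets the difference was 2.57 for Csn2, -1.35 for Slc16a9 and -1.90 for Flrt1.

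In lymph node 6 lists rose in knockout. The proliferation list rose by a mean of 1.22 (17 of 18 higher; adjusted p = 7.70e-06; adjusted p = 0.699 with an estimated correlation), with the spindle checkpoint kinase Bub1 at 2.77, Nusap1 at 2.50 and Birc5 at 2.28. Its mean log2 signal was 8.01 on knockout array A and 6.69 on B, against 6.60 and 5.65. The macrophage list rose by 1.35 (13 of 15 higher; adjusted p = 0.00015; adjusted p = 0.699 with an estimated correlation), with Siglec1 at 4.07 and Adgre1 at 2.13, both surface proteins of tissue macrophages. Its mean log2 signal was 8.89 and 7.85 in knockout, against 7.69 and 6.35. The interferon-gamma list rose by 0.81 (9 of 12 higher) and the type I interferon list by 0.62 (14 of 16 higher), each with adjusted p = 0.000183 and adjusted p = 0.16 with an estimated correlation. Their members with the smallest p included Gbp6 (1.69), Iigp1 (2.95), Igtp (1.03), Rtp4 (1.87) and Irf7 (1.40), with Mx1 lower at -0.97.

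The list of thymic tissue antigens that depend on Aire rose in knockout lymph node by a mean of 1.94 (4 of 4 tested members higher; adjusted p = 0.000274; adjusted p = 0.16 with an estimated correlation). The tested members were Csn2 at 4.04 or more, Pcp4 at 1.86, Svs5 at 0.82 and Sst at 1.06. Of the 21 measured members 17 lay at or under the filter level on every array, and Csn2 passed the filter through its knockout arrays alone. Without the floor the mean over the 4 was 1.25 (adjusted p = 0.148). The chemokine and cytokine list rose by 0.47 (12 of 22 higher; adjusted p = 0.0322; adjusted p = 0.435 with an estimated correlation), with Il10 at 2.24 and Ccl6 at 1.92. Over all genes tested, 0 members of the 6 lists passed. Adjusted over the list alone, 2 macrophage, 2 interferon-gamma, 2 chemokine, 1 proliferation and 1 tissue antigen gene passed, all higher: Siglec1, Adgre1, Gbp6, Iigp1, Il10, Ccl6, Bub1 and Csn2. Among blood endothelial genes, a list that did not pass (adjusted p = 0.595), Tek was lower at -2.0 and passed over the list alone.

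By limma 0 of 11557 genes passed in lymph node, and 391 had an unadjusted p under 0.05, 201 higher and 190 lower, fewer than the 578 that chance gives. With all probe sets tested 3 without a gene name passed, and 30.9% of genes had groups that did not overlap, against 33.3% by chance. Without knockout array A the macrophage mean was 0.83 (adjusted p = 0.0847) and the proliferation mean 0.56 (adjusted p = 0.105). Without wild-type array B, 3 lists passed, with macrophage at 0.68 (adjusted p = 0.171), proliferation at 0.75 (adjusted p = 0.0895) and chemokines at 0.37 (adjusted p = 0.171). Without knockout array B the chemokine mean was 0.39 (adjusted p = 0.29), and without wild-type array A 9 lists passed. The chemokine list also missed without a filter (adjusted p = 0.0741) without median scaling (adjusted p = 0.0765) and with the Y-linked genes as a covariate (adjusted p = 0.0874), and the type I interferon list with a stricter filter (mean 0.21, adjusted p = 0.205).

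The knockout effect was also averaged over the tissues, with 4 arrays against 4. By camera at its preset correlation, macrophage, proliferation, interferon-response, costimulatory, chemokine, tissue antigen, plasma cell and platelet genes were higher as groups in knockout, and epithelial genes lower. None of these 10 lists passed with an estimated correlation, the lowest adjusted p = 0.248 and the highest adjusted p = 0.623, and all but the macrophage, proliferation and interferon-gamma lists were also lost in at least 1 other processing or with 1 array left out. The proliferation list was lost with both knockout A arrays left out (mean 0.39), which sets knockout B arrays against wild-type A and B arrays. Plau and C5ar1 had the smallest p, and their signals were higher on all 4 knockout arrays than on the wild-type arrays of the same tissue. No single gene passed.

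Plau was higher in knockout by 2.89 ± 0.27 (7.40-fold), with signals of 369 and 399 against 41.6 and 52.9 in spleen, and 1000 and 690 against 157 and 98.3 in lymph node. C5ar1 was higher by 4.57 ± 0.45 (23.7-fold), Rnase4 by 2.22 ± 0.25 (4.66-fold) and Fcgr2b by 2.19 ± 0.26 (at least 4.56-fold). Csn2 lay at the floor on all 4 wild-type arrays and was higher by 3.25 ± 0.39, at least 9.53-fold. Wnt10b lay at the floor on all 4 knockout arrays and differed by -2.69 ± 0.30, at least 6.47-fold. Chadl differed by -1.84 ± 0.24 (3.59-fold), Fam228b by -2.32 ± 0.32 (5.01-fold), Slc16a9 by -1.82 ± 0.25 (3.52-fold) and Pkp2 by -2.17 ± 0.31 (4.50-fold). The limma adjusted p was 0.114 for Plau and C5ar1, 0.128 for Rnase4 and Wnt10b, 0.13 for Fcgr2b and Csn2, 0.148 for Chadl and 0.152 for Fam228b, Slc16a9 and Pkp2. For the mean of a gene's probe sets the averaged difference was 2.65 for C5ar1, 2.18 for Csn2 and -1.54 for Pkp2.

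**Figure D2:**
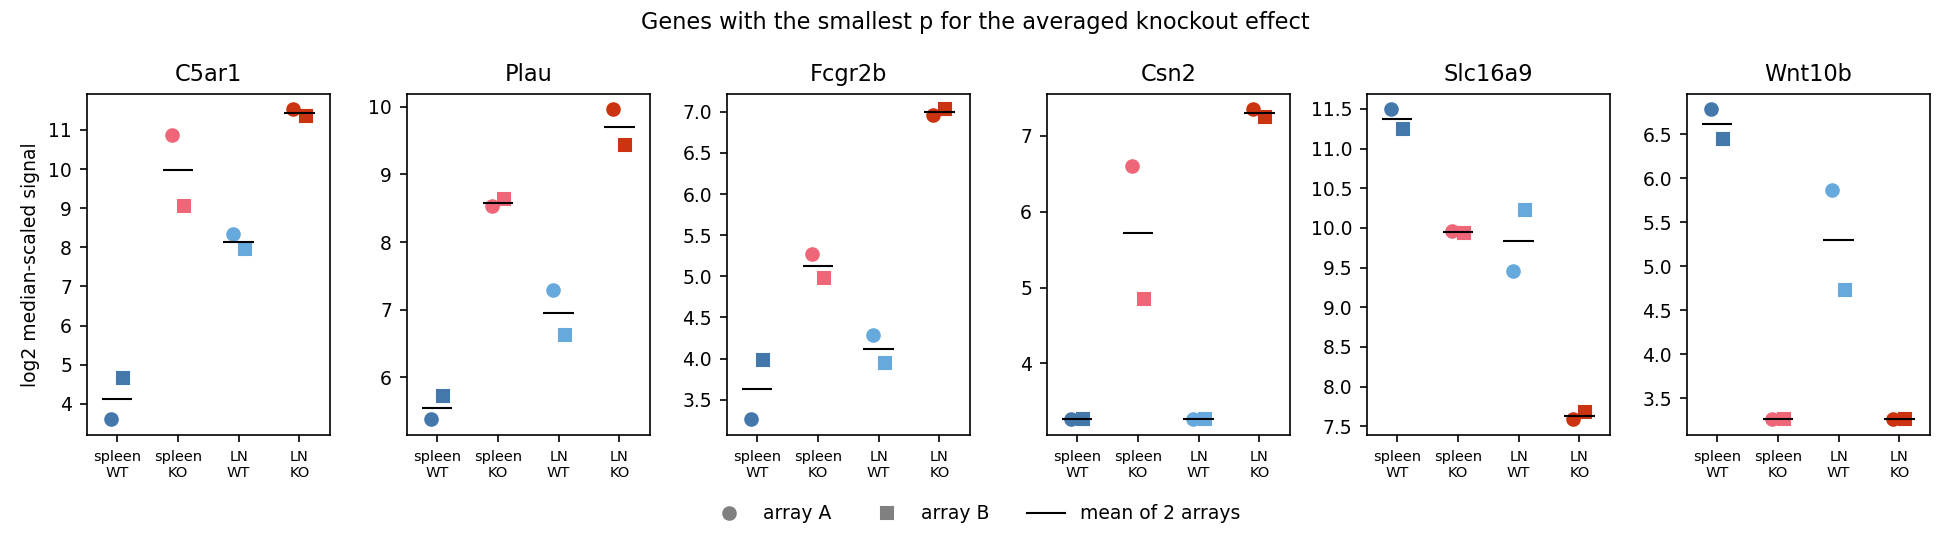
Signal of 6 genes on each of the 8 arrays, on a log2 axis after scaling to a common median; points are arrays (circle A, square B) and lines are means of 2 arrays. C5ar1, Plau, Fcgr2b and Csn2 lie higher and Slc16a9 and Wnt10b lower on both knockout arrays of each tissue, with averaged differences of 4.57, 2.89, 2.19, 3.25, -1.82 and -2.69; none passed correction.

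Among the 10 lists that passed for the averaged effect, the proliferation list rose by a mean of 1.28 (18 of 18 tested members higher; adjusted p = 4.96e-08; adjusted p = 0.411 with an estimated correlation), with Bub1 at 1.77, Nusap1 at 2.71, Top2a at 1.39 and Mcm2 at 1.03. The macrophage list rose by 1.5 (13 of 15 higher; adjusted p = 6.26e-06; adjusted p = 0.411 with an estimated correlation), with Siglec1 at 3.33, Adgre1 at 1.65, Cd5l at 3.25 and the complement gene C1qc at 2.62, while Spic and Marco were lower at -0.61 and -0.40. Without knockout array A of spleen the 2 means were 0.72 and 0.96, and with both knockout A arrays left out 0.39 (adjusted p = 0.0504) and 0.70 (adjusted p = 0.0182). The type I interferon list rose by 0.62 (14 of 16 higher; adjusted p = 0.000292) and the interferon-gamma list by 0.74 (9 of 12 higher; adjusted p = 0.000362), each with adjusted p = 0.248 with an estimated correlation. Their leading members were Rtp4 (1.69), Irf7 (1.91), Oasl2 (2.35), Iigp1 (3.26), Igtp (1.34) and Gbp6 (1.25), and Mx1 was lower at -1.06. With a stricter filter the type I interferon mean was 0.08 (adjusted p = 0.444).

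The costimulation list rose by a mean of 0.48 (12 of 14 higher; adjusted p = 0.00358; adjusted p = 0.411 with an estimated correlation), with Cd86 at 1.41 and Tnfrsf14 at 1.16. It missed with the Y-linked genes as a covariate (mean 0.35, adjusted p = 0.0742) and with both knockout B arrays left out (adjusted p = 0.0696), and in lymph node alone its mean was 0.20 (adjusted p = 0.445). The tissue antigen list rose by 1.41 over its 4 tested members (adjusted p = 0.00545) and the chemokine list by 0.51 (14 of 22 higher; adjusted p = 0.00545), each with adjusted p = 0.259 with an estimated correlation. Ccl3 was higher by 2.33, Il10 by 2.23, Ccl2 by 1.5 and Ccl6 by 1.06. The plasma cell list rose by 0.92 (7 of 8 higher; adjusted p = 0.029; adjusted p = 0.623 with an estimated correlation), with Prdm1 at 1.13 and Mzb1 at 1.93. The platelet list rose by 1.57 (3 of 3 higher; adjusted p = 0.0307; adjusted p = 0.411 with an estimated correlation), with Pf4 at 3.28; in lymph node alone its mean was 0.44 (adjusted p = 0.557). The epithelial list fell, with a mean of -0.51 (6 of 7 lower; adjusted p = 0.0454; adjusted p = 0.411 with an estimated correlation); Epcam was lower at -1.02, Krt18 at -0.81 and Krt8 at -0.91. Over all genes tested 0 members of the 10 lists passed. Adjusted over the list alone, the numbers passing were 4 higher and 1 lower for type I interferon (Rtp4, Irf7, Oasl2 and Oasl1 at 0.92, and Mx1), 3 for interferon-gamma (Iigp1, Igtp, Gbp6), 4 for chemokines (Il10, Ccl2, Ccl6, Ccl3), 2 for macrophage (Siglec1, Adgre1), and 1 each for proliferation (Bub1), tissue antigens (Csn2) and platelets (Pf4).

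By limma 0 of 11557 genes passed for the averaged effect, and 924 had an unadjusted p under 0.05, 422 higher and 502 lower, against 578 by chance; without median scaling 546 of 950 were higher. With a trended robust prior 6 genes passed, C5ar1, Plau, Retnla (3.83), Cd7 (-1.65), Slc16a9 and Aire; a 40th percentile floor gave 2, a stricter filter 3 and all probe sets 3, and 2 genes, C5ar1 and Csn2, passed without spleen knockout array B. All arrays of one genotype lay apart from all of the other in 423 genes, 3.66% of those tested, where chance gives 2.86%. Without spleen knockout array A, 7 lists passed, and the epithelial (adjusted p = 0.462), plasma cell (adjusted p = 0.535) and platelet lists (adjusted p = 0.104) did not. Those 3 also missed without spleen wild-type array B (each adjusted p = 0.19) and without lymph node knockout array A (adjusted p = 0.0512, 0.0512 and 0.0967). Without lymph node wild-type array B the plasma cell (adjusted p = 0.225) and platelet lists (adjusted p = 0.0986) missed, the epithelial list missed without wild-type array A (adjusted p = 0.111) or knockout array B of lymph node (adjusted p = 0.085), and the chemokine list missed without the latter (adjusted p = 0.0599). With all 21 measured members in the test the tissue antigen mean was 0.17 (adjusted p = 0.663), and without the floor 0.94 (adjusted p = 0.261). The plasma cell, platelet and epithelial lists each missed in at least 3 other processings, with adjusted p from 0.0512 to 0.151.

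**Figure D3:**
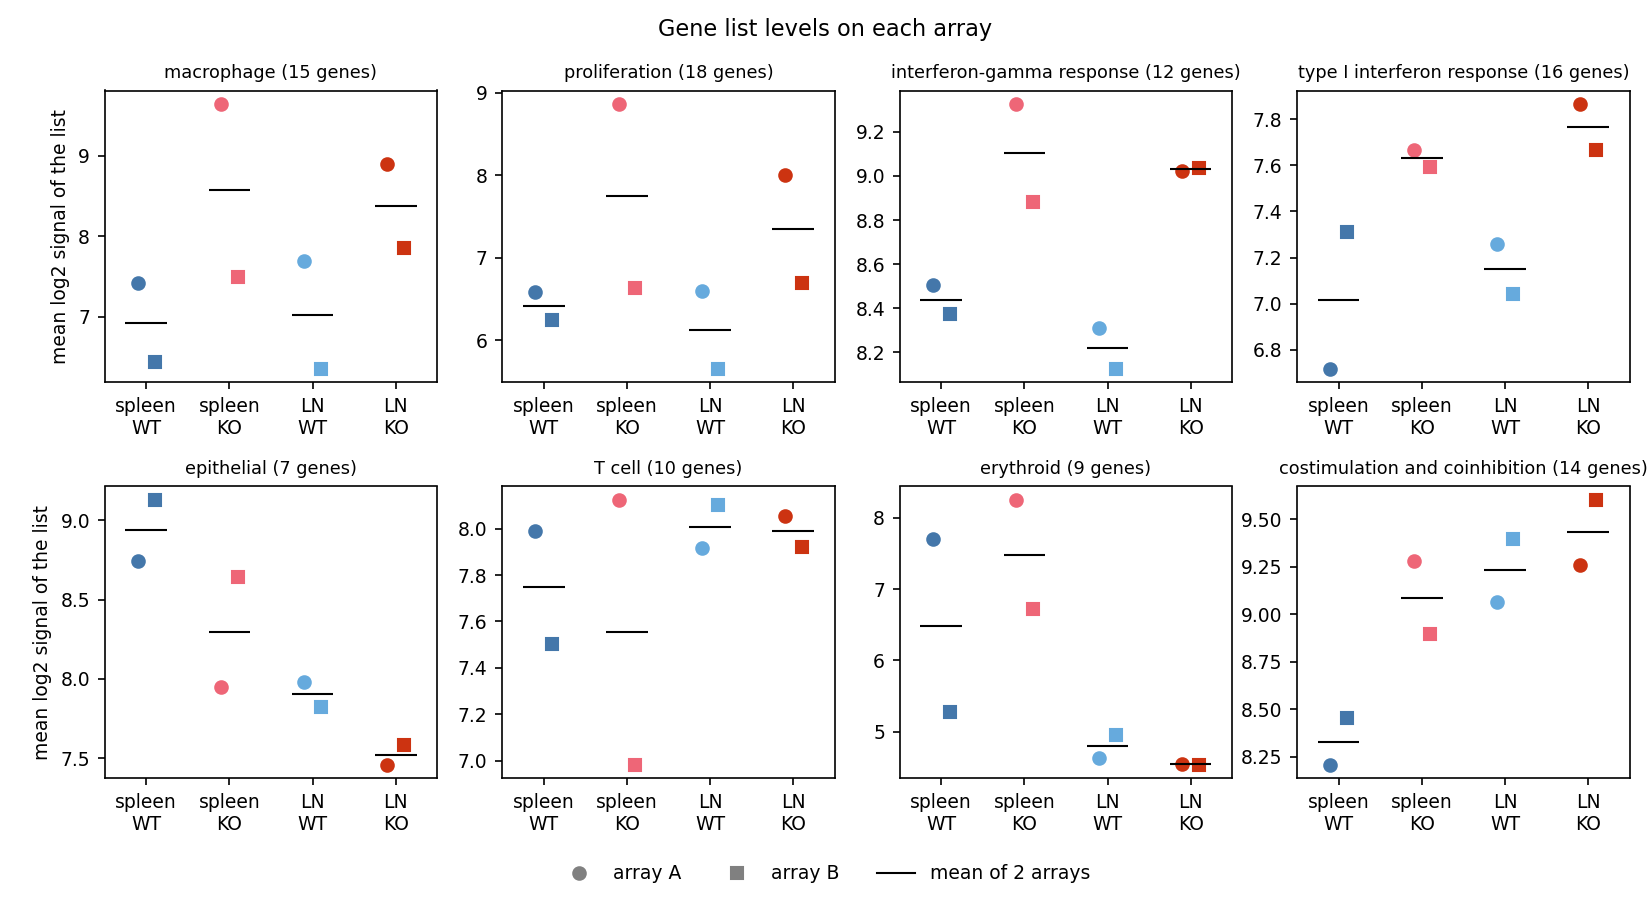
Mean log2 signal of the tested members of 8 gene lists on each of the 8 arrays, after scaling to a common median; points are arrays (circle A, square B) and lines are means of 2 arrays, on a separate axis for each list. The macrophage list averages 9.65 on spleen knockout array A and 6.35 to 8.89 on the other 7 arrays.

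Whether the knockout effect differed between spleen and lymph node was tested directly. The effects shared a direction more often than not, and no gene or list passed the test of their difference. By limma 0 genes passed (lowest adjusted p = 0.999), and 395 had an unadjusted p under 0.05, 176 of them with a higher effect in spleen, where chance gives 578. The lowest adjusted p among lists was 0.149, for costimulation. The genes with the smallest p and a higher effect in spleen were Cldn1, a tight junction protein, with a difference of 2.95 ± 0.45, Tceal1 (2.45 ± 0.41), Cpq (2.95 ± 0.50), Tmem156 (4.25 ± 0.74) and Havcr2 (3.23 ± 0.58). All 5 had 1 or both wild-type spleen arrays at the floor, so these differences are lower bounds. Those with a lower effect in spleen were Foxd1 (-3.04 ± 0.47), Tmem258 (-3.07 ± 0.51), Gstm4 (-2.65 ± 0.46), Ccnk (-3.97 ± 0.83) and Ifna1 (-2.93 ± 0.63), with 1 wild-type lymph node array at the floor for Ccnk. Foxd1 lay at the floor on 3 of 4 spleen arrays, so its effect in spleen was not measured. Without single arrays Tmem156 ranged from 3.57 to 4.94 and Ccnk from -4.75 to -3.19. For the mean of its probe sets Tmem258 was at -1.77. Between 0 and 4 lists passed when single arrays were left out, with 4 without spleen knockout array B and 1 without spleen wild-type array A or lymph node knockout array B.

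Across the 11557 genes the knockout effects in spleen and lymph node, which share no array, had a Pearson correlation of 0.32 and a Spearman correlation of 0.26, and 59.9% of genes had the same sign. Genes are not independent replicates, so no p is given. Of the genes at an unadjusted p under 0.05, 57 were higher in knockout in both tissues, where independent lists would share 7.76. In both tissues 50 were lower, against 8.66. Both tests of a gene used the same estimate of its spread, so a gene with a small spread can reach that p in both. The numbers for independent lists are therefore not a baseline for chance. Shared higher genes included Plau, C5ar1, Fcgr2b, Csn2, Siglec1, Adgre1, the macrophage scavenger and mannose receptors Msr1 and Mrc1, the chemokines Ccl2, Ccl3, Ccl7 and Ccl8, Il10, Tlr4, Iigp1, Igtp and Gbp6. Shared lower genes included Aire, Wnt10b, Slc16a9, Pkp2, Chadl, Fam228b, Cd7 and the circadian gene Dbp. The covariance of the effects was 0.15, against 0.08 from the deviations that arrays of the same genotype and letter had in common. The correlation was 0.14 without spleen knockout array A, 0.15 without lymph node knockout array A and 0.20 without lymph node wild-type array B.

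Spleen and lymph node arrays were also compared with each other, averaged over genotypes. By camera at its preset correlation, red cell, epithelial and blood endothelial genes were higher as groups in spleen, and costimulatory and chemokine genes in lymph node. None of these 5 lists passed with an estimated correlation, the lowest adjusted p = 0.459 and the highest adjusted p = 0.576. The nearest gene to the threshold was Tceal1, lower in spleen. No single gene passed correction.

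Nav2 was higher in spleen by 2.35 ± 0.27 (5.08-fold), the nuclease Dnase1l3 by 1.63 ± 0.21 (3.09-fold), Slc16a9 by 1.92 ± 0.25 (3.80-fold), the ubiquitin-like gene Ubd by 1.90 ± 0.26 (3.74-fold) and Maob, a monoamine oxidase, by 3.80 ± 0.53 (at least 13.9-fold). Tceal1 was lower in spleen, at -2.56 ± 0.20, at least 5.92-fold, with both wild-type spleen arrays at the floor. Olfm1 was lower at -2.47 ± 0.26 (5.53-fold), the pseudokinase Trib2 at -1.80 ± 0.20 (at least 3.49-fold, with the same arrays at the floor), Calm4 at -3.34 ± 0.38 (10.1-fold) and Lrrc1 at -1.79 ± 0.21 (at least 3.45-fold). The limma adjusted p was 0.0575 for Tceal1, 0.127 for Maob and 0.115 for the other 8 genes. For the mean of a gene's probe sets the tissue difference was 1.26 for Nav2, 1.17 for Slc16a9 and -1.53 for Olfm1. Aire was higher in spleen by 0.67 ± 0.33 (adjusted p = 0.523).

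In camera tests 5 lists differed between the tissues. The erythroid list was higher in spleen by a mean of 2.31 (9 of 9 higher; adjusted p = 0.00027; adjusted p = 0.576 with an estimated correlation), with the red cell membrane anion exchanger Slc4a1 at 5.45, Hemgn at 4.29, the transcription factor Klf1 at 2.46 and Rhd at 2.39. Its mean log2 signal ranged from 5.27 to 8.25 on the spleen arrays. The epithelial list was higher by 0.91 (7 of 7 higher; adjusted p = 0.00379; adjusted p = 0.459 with an estimated correlation), with Cdh1, or E-cadherin, at 2.18 and Cldn7 at 1.42. The blood endothelium list was higher by 0.77 (7 of 7 higher; adjusted p = 0.0142; adjusted p = 0.459 with an estimated correlation), with the receptors Tek at 1.61 and Kdr at 1.15. The costimulation list was lower in spleen, with a mean of -0.62 (11 of 14 lower; adjusted p = 0.0013; adjusted p = 0.485 with an estimated correlation); Cd86 was lower at -1.93, Tnfsf4 at -1.64, Cd80 at -1.45 and Tnfsf9 at -1.09. The chemokine list was lower, with a mean of -0.52 (15 of 22 lower; adjusted p = 0.00386; adjusted p = 0.459 with an estimated correlation), and Il12b was lower at -2.63. Over all genes tested 0 members of these lists passed. Adjusted over the list alone, 6 erythroid, 2 epithelial (Cldn7, Cdh1), 2 endothelial (Tek, Kdr), 5 costimulatory (the 4 named and Cd274) and 5 chemokine genes passed, the last with Il12b, Cxcl2 (-1.21) and Ccl2 (-1.16) lower and Lta (1.14) and Ccl9 (1.06) higher.

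By limma 0 of 11557 genes passed between tissues, and 1242 had an unadjusted p under 0.05, 720 higher and 522 lower in spleen, where chance gives 578; without median scaling 531 of 1287 and with quantile normalization 609 of 1279 were higher. With a trended robust prior 48 genes passed, Dnase1l3 and Nav2 among them, and between 0 and 3 in other settings. The tissues did not overlap in 661 genes, 5.72%, where chance gives 2.86%. The blood endothelium list missed without lymph node knockout array B (adjusted p = 0.0888), lymph node wild-type array B (adjusted p = 0.156) or spleen wild-type array A (adjusted p = 0.0972), and the epithelial list without spleen knockout array B (adjusted p = 0.101). With a stricter filter 3 lists passed, without the epithelial (adjusted p = 0.0736); the blood endothelium list also missed without a filter (adjusted p = 0.0556) or with a 40th percentile floor (adjusted p = 0.101).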

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

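The limma tests and the counts of all splits below were planned; every test that weighs an explanation other than chance was chosen after the results were seen.

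6 named genes moved one way on both knockout arrays of spleen and the other way on both of lymph node. The difference of the spleen and lymph node effects was -2.65 for Gstm4 (spleen -2.20, lymph node 0.45), 2.95 for Cldn1 (1.45 and -1.51), 2.45 for Tceal1 (1.01 and -1.45), -3.97 for Ccnk (-1.97 and 2.0), -2.93 for Ifna1 (-1.84 and 1.1) and 1.89 for Trib2 (1.74 and -0.15). The limma test of the difference gave each of the 6 an adjusted p = 0.999. All but Trib2 had been named for a small p in that same difference, so their opposite movement largely restates the choice. How many of all genes tested moved in this way was not counted, and with 2 arrays per group many would by chance. Wild-type spleen arrays lay at the floor for Tceal1 and Trib2 (both arrays) and Cldn1 (1 array), and 1 wild-type lymph node array did for Ccnk, so these differences are lower bounds.

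2 probe sets that carry no gene name in the table used here, and so entered no comparison of genes, were at or near the floor in wild-type and bright in knockout arrays. The first was at the floor on 3 of 4 wild-type arrays, with a highest signal of 13.7, and ranged from 1749 to 4568 on the knockout arrays, an averaged difference of at least 8.00 ± 0.24 (at least 8.73 in spleen and 7.27 in lymph node; limma adjusted p = 7.63e-05 over 26479 probe sets). The second was at the floor on 4 of 4 wild-type arrays and ranged from 1791 to 4521, an averaged difference of at least 8.20 ± 0.22, or 294-fold (8.82 and 7.58 in the tissues, lower bounds too; adjusted p = 5.62e-05). A further unnamed probe set was called, higher by at least 4.75 ± 0.26 (adjusted p = 0.00282). These were the only 3 called for the averaged effect among all probe sets.

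The number of genes at an unadjusted p under 0.05 was compared with other splits of the 8 arrays. With tissue as a term, knockout against wild-type gave 956 genes, and 4 of 34 splits gave as many, the highest of the others 1443, so chance cannot be excluded for that count. The split by letter was one of the 4, with 986 genes. With genotype as a term, spleen against lymph node gave 1324 genes, and 3 of 34 splits gave as many, the highest of the others 1494, so chance cannot be excluded there either. Of the 8 splits with 1 array of each genotype and letter on a side, chosen after the match below was seen, the real one had the most genes and the next 672, but 8 splits are too few for a share under 0.05.

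The macrophage list was higher in knockout arrays by a mean of 1.5 over the tissues, a call lost with an estimated correlation (adjusted p = 0.411), and the A array exceeded the B array in 4 of 4 groups by 0.98 to 2.15, about as much as the genotypes differed. Without median scaling the mean was 1.57, so the median shift did not make the difference. That shift was small, and the scaling done before deposition stayed in place and was not tested. With the Y-linked genes as a covariate the mean was 2.15. Neither change ended the call at the preset correlation. Eif2s3y was lower on A than on B in every group, so the covariate also stands in for the letter and cannot decide on sex. A lower share of the main cell type would raise the markers of other types alike. The list rose more than the mean of 12 other cell type lists, by 1.08 (95% interval 0.03 to 2.13), but the interval was above 0 for only 3 of the 12 singly. With 1 value per genotype and letter the interval was -1.12 to 3.27. That interval leaves out the letter, so its width holds the A to B difference too, and it cannot decide. The values were 1.69 (A) and 0.98 (B) in knockout, and 0.62 (A) and -0.11 (B) in wild-type, so knockout was higher at either letter. The macrophage list did not rise more than the neutrophil and monocyte list (difference -0.02) or the platelet list (-0.07). A lower share of the main cell type therefore stays open. RNA of more macrophages cannot be told apart from a change within cells: the 13 of 15 tested markers that were higher only restate the list result, and the abundant C1qa (3.13 ± 1.49), C1qb (2.13 ± 1.0), C1qc (2.62 ± 1.11), Csf1r (2.99 ± 1.5) and Lyz2 (2.0 ± 1.09) each had an unadjusted limma p over 0.05. A difference in handling between the genotypes was not tested.

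Aire was lower in knockout arrays, at -1.76, yet its signal stayed at 791 or more. A lower share of the cells that carry the dendritic cell list's genes would lower those genes as much, but 8 members bright on all arrays had a median of -0.0567 (SD over members 0.37), and the lowest was Ccr7 at -0.43. For cells that carry the epithelial list's genes, the median of 7 tested members was -0.40 (SD over members 0.45), and the lowest was Epcam at -1.02. Both medians argue against an even loss of all such cells as the whole cause, though the SD is over genes and not over samples. They cannot show the loss of a smaller group of these cells that carries Aire, since the remaining cells would hold the medians up. The epithelial list was itself called lower by camera at the preset correlation (mean -0.51). The deletion itself stays open, and so does a loss of cells marked by other genes, which was not tested.

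Sex-linked genes differed between arrays of a group in the same way in both tissues, which may mean that a spleen and a lymph node array of the same genotype and letter come from the same animals. The distance in Xist and the 3 Y-linked genes was smallest for the match by genotype and letter (4.92, next 6.70), but that restates the observation. Over the other tested genes, 1 of the 4 matches that keep genotype had as high a summed correlation as the match by letter, that match itself (0.84, next 0.71), and 4 matches are too few for an exact p under 0.25, so whether they come from the same animals stays open. Xist together with Y-linked signal on 4 arrays could come from pooled animals of both sexes, which was not tested. If the animals are shared, the spleen and lymph node effects are not independent, and the correlation between them may be raised by it.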

How the results depend on the processing

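Alternatives added after the data were seen were the genotype and letter blocks, the Y-linked covariate, leaving out both arrays of a letter, and the letter together with an estimated correlation. Of 3583 alternative values of named genes, 3558 kept their direction and side of the threshold, 25 came to pass and 0 reversed; of 741 for lists that passed, 604 kept both, 136 no longer passed and 1 reversed, the type I interferon list in spleen with a stricter filter (-0.0475). Causes were not tested, except that fewer tests and fewer genes per list follow from the filters. Named genes were chosen for a small p in these arrays and none passed. The count for genes was thus largely fixed by that choice and says little about size. The size of a dim gene's difference depends on the floor: with a 40th percentile floor the averaged difference was -0.93 for Wnt10b and 1.45 for Csn2. With that floor Gstm4 in spleen went from -2.20 to -0.82 and Npvf in lymph node from -2.36 to -0.49.

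Genes called between tissues numbered 1 with quantile normalization, no median scaling, no filter, the mean of probe sets or the genotype and letter random block, 3 with a 40th percentile floor and 48 with a trended robust prior. For the averaged effect they numbered 2 with a 40th percentile floor, 3 with a stricter filter, 3 with all probe sets and 6 with a trended robust prior. In spleen they numbered 2 with all probe sets and 1 with a trended robust prior, and in lymph node 3 with all probe sets. Lists called numbered 0 in spleen, lymph node, the average and between tissues with an estimated correlation, with or without the letter as a term. A stricter filter gave 5 lists for the average and 3 between tissues. For the difference of effects, no median scaling, a stricter filter and all probe sets each gave 1, and leaving out both knockout B arrays 2. In spleen the Y-linked covariate gave 11 lists and leaving out both knockout A arrays 2.

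The correlation between tissues was 0.23 with no filter, 0.43 with a stricter filter, 0.50 with the Y-linked covariate, 0.13 without both knockout A arrays and 0.45 without both knockout B arrays. With single arrays left out, where the lone array of a group is assumed to vary like the others, it ranged from 0.14 to 0.36. Lists then ranged from 2 to 11 in spleen, 3 to 9 in lymph node, 7 to 11 for the average, 0 to 4 for the difference and 4 to 7 between tissues, and genes called for the average from 0 to 2. Aire differed by -2.34 to -1.11 in spleen, -2.05 to -1.53 in lymph node and -2.07 to -1.45 on average.

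With the letter as a replicate block, 0 genes passed in all 5 contrasts, and 10, 7, 11, 0 and 6 lists passed in spleen, lymph node, the average, the difference and between tissues. By limma 1208 genes then had an unadjusted p under 0.05 in spleen, 532 in lymph node and 1148 for the average, against 973, 391 and 924 without the letter. The A minus B differences of 2 groups correlated at 0.06 to 0.31 across genes, all above 0 and 3 of 6 over 0.1. Some of the A to B difference was thus shared between groups. The main tests assumed no pairing because the labels do not say what the letters mark, and that stays open.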

Other observations

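MHC presentation genes and most dendritic cell markers were bright on all 8 arrays. All 12 measured members of the MHC class II presentation list, 15 of 15 of the class I list, 8 of 12 dendritic cell markers and 8 of 10 plasmacytoid dendritic cell markers lay above the filter level on all 8 arrays, while 6 of 15 macrophage, 1 of 12 B cell, 1 of 15 stromal and 3 of 12 epithelial markers did so; 2 of the 12 dendritic cell markers lay above it on no array. Ccr7, the receptor that guides dendritic cells to lymph nodes, had signals from 8241 to 14750, and the actin-bundling gene Fscn1 from 9491 to 12480. Aire itself lay above 98.1% of genes in wild-type spleen and 96.8% in wild-type lymph node arrays. These levels were not compared with those of whole tissue. In the averaged knockout effect the dendritic cell and MHC lists did not pass, with adjusted p = 0.663 for dendritic cell, 0.916 for plasmacytoid dendritic cell, 0.382 for class I and 0.916 for class II genes. Their mean differences were 0.15, 0.09, -0.15 and 0.01.

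The T cell list did not pass in knockout spleen (mean -0.19, adjusted p = 0.518). The differences of its members had both signs, with Cd8a at 2.19, Cd4 at 2.0, Cd3e at -2.36, Cd3d at -1.26 and Zap70 at -1.05, and none passed over the list alone. Spleen knockout array A stood apart in neutrophil genes, with S100a8 at 2954 and S100a9 at 4833, where the other 7 arrays lay between 9.58 and 94.5 and between 9.58 and 297. The neutrophil and monocyte list did not pass in spleen (mean 1.95 over 3 genes, adjusted p = 0.151) or in the average (adjusted p = 0.135). Among the spleen arrays, knockout A also had the highest mean log2 signal of the B cell (7.54), plasma cell (10.2), T cell (8.12), NK cell (6.82), erythroid (8.25) and platelet (8.48) lists. It had the lowest of the epithelial (7.95) and mast cell (6.24) lists, and was not highest for blood endothelium or stroma. Its Aire signal, 1009, was the lowest in spleen.

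Of the other lists, none passed for the averaged knockout effect. Their mean differences and adjusted p were 0.44 and 0.205 for B cell, -0.11 and 0.592 for T cell, 0.05 and 0.827 for NK cell, 0.37 and 0.248 for erythroid, 0.01 and 0.916 for mast cell and basophil, 0.05 and 0.911 for blood endothelium, 0.53 and 0.262 for lymphatic and high endothelium, and 0.20 and 0.65 for fibroblastic reticular and stromal genes. They were 0.08 and 0.911 for the medullary thymic epithelial and NF-kB program, -0.01 and 0.827 for Aire partners, -0.12 and 0.262 for immediate early and heat shock genes, 0.10 and 0.65 for apoptosis regulators, -0.10 and 0.663 for ribosomal proteins and -0.04 and 0.911 for oxidative phosphorylation. The mean was above 0 and the median below it for the NK cell, plasmacytoid dendritic cell, mast cell, stromal, class II, NF-kB and apoptosis lists, and the class II and NF-kB lists ranked lower by camera with a mean above 0. No list that passed in any contrast had a mean and a median of opposite sign. In lists that did not pass, Tek was lower in the averaged knockout effect at -1.43, and Cr2 (1.55) and Ido1 (2.27) were higher in spleen than in lymph node, each past the test adjusted over the list alone. The fry test gave no list an adjusted p under 0.05 in any of the 5 contrasts, with 0.0897 the lowest.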
